A study of Canis lupus familiaris with 24 samples.

How the data were processed

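The deposited table held whole-number counts per gene, with 1 column for each of the 24 libraries and no normalization. Per the submitters' processing notes, the tools were STAR 2.5.3a, RSEM 1.3.0 and FastQC with the dog genome build CanFam3.1. The role and order of these tools are not given in the sources used here, nor is it stated whether RSEM estimates were rounded, which annotation release was used or which strand setting was chosen. The table listed 32704 Ensembl dog genes, of which 18660 carried a symbol and 14044 did not. There were 19857 protein-coding genes and 8124 long intergenic RNA genes. Gene symbols were taken from that table. A second gene table used here describes another dog assembly without Ensembl identifiers, so genomic positions are not given.

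Each library was placed in its group by the library number in its label, and every column matched 1 sample. The 8 groups were MDCK-II and MDCK-NBL2 cells untreated at day 0, untreated at day 4 and treated with TGFb to day 4, and TGFb-treated MDCK-NBL2 cells that also received a control siRNA (siCTR) or an siRNA against PRRX1 (siPRRX1). All 24 libraries were kept, with 3 per group. Total counts ran from 6134929 to 27567296 per library. The dose unit of TGFb printed in the labels is doubtful and is left out here. The labels number the replicates but do not say whether they are separate cultures, so the p-values measure the spread between these libraries.

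Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests. A single model with a mean per group was fitted to all 24 libraries, leaving 16 residual degrees of freedom. Library sizes were scaled by TMM, and filterByExpr with a minimum count of 10 and a minimum total of 15 left 12466 genes. The prior count was 0.125, and the common biological coefficient of variation was 21.9%. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. Log2 fold changes are given with a standard error (SE) derived from the test, as the size of the log2 fold change over the square root of the F statistic. Levels are counts per 1000000 (CPM) on TMM-scaled library sizes, as mean and SD of 3 libraries. Where a group had no count in any of its libraries, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval, and these bounds cover counting error only.

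Gene lists were written from general knowledge before the data were examined, as were the tests, the rule for named genes and the alternative settings fixed in advance. There were 22 lists with 641 genes, of which 585 were in the table. They covered EMT transcription factors, epithelial adhesion and junctions, epithelial regulators and keratins, and mesenchymal cytoskeleton and adhesion. Matrix lists covered collagens, matrix glycoproteins and proteoglycans, matrix proteases with their inhibitors and crosslinkers, and integrins. Signalling and state lists covered the TGF-beta pathway, cytokines with chemokines and NF-kB targets, the interferon response, the cell cycle, and CDK inhibitors with p53 targets. They also covered renal tubule transport and identity, YAP and TEAD targets, Wnt targets and inhibitors, cholesterol synthesis, the ATF4 stress response, and hypoxia with glycolysis. Marker lists of fibroblasts, endothelial cells and leukocytes stood for other cell types. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation. Of 198 list tests, 69 passed at the preset correlation and 2 of these passed with the estimated correlation, the Wnt list in the difference of TGFb responses and in the untreated lines at day 4.

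The rule named PRRX1 and SNAI1 in every comparison. In each of the 4 main comparisons it named the tested EMT transcription factors, the 6 largest rises and 6 largest falls, and up to 4 members per list with the smallest adjusted p. In the 5 secondary comparisons it named 3 rises, 3 falls and up to 3 members per list. The largest changes had to have a symbol, an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between 2 groups of 3 libraries, which chance alone gives in 10% of genes. For overlaps it named up to 6 genes per direction. Of the genes so named, 2 are not reported here and no others took their place, while list results still include them. Genes named outside this rule are marked as chosen after their values were seen.

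The alternative settings fixed in advance were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, no filter on low counts, a replicate block, the library number series as a term, only the groups compared, each library of the groups compared left out in turn, and for overlaps a 2-fold minimum. The alternatives added after seeing the data left out the library labelled MDCK-NBL2 untreated day 4 replicate 2, or MDCK-NBL2 day 0 replicate 1, or 3 day 4 untreated libraries, or combined the replicate block with only the groups compared. Whether replicate numbers pair libraries was checked by correlating the deviations of the libraries from their group means across genes. Libraries with the same number went together in the TGFb comparison of MDCK-II (0.47, 0.29 and 0.37 for replicates 1, 2 and 3), in the siPRRX1 comparison (0.40, 0.25 and 0.21) and between the untreated lines at day 0 (0.13, 0.14 and 0.25), and blocked counts stand beside those results. The number series in the library names, 26 for 19 libraries and 58 for 5, is not described as a batch in the labels. Switching to DESeq2 size factors moved the median log2 fold change of all genes by at most 0.021 in size.

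The whole procedure was tested on simulated data with the library sizes and dispersions of these libraries. Apart from the simulated changes, each gene had the same mean and the same dispersion in every group. No library departed from its group and no libraries were paired. The shares and false calls that follow hold for such data, and not for groups with a departing library. For the TGFb comparison in MDCK-II it recovered 56.2% of genes simulated with a 2-fold change and 84.0% of those with a 4-fold change, and 3 of 141 calls were false. For the siPRRX1 comparison the shares were 56.2% and 85.9%, with 7 false among 146 calls. For the difference of the TGFb responses they were 29.3% and 72.7%, with 4 false among 105 calls. Within each group no 2 libraries were copies of each other. Pairs of libraries from different groups were not checked for copies. Protein levels, cell shape and migration were not analysed here.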

Results

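RNA was sequenced from cultured MDCK cells, an epithelial line from dog kidney, as 24 stranded mRNA libraries. The sublines MDCK-II and MDCK-NBL2 were sampled untreated at day 0, untreated at day 4 and at day 4 with TGFb, a cytokine that drives epithelial-mesenchymal transition (EMT), in which epithelial cells loosen their junctions and turn to matrix and contractile genes. Treated MDCK-NBL2 cells were also given an siRNA, a short RNA that silences a target transcript, either a control siRNA (siCTR) or siPRRX1 against the transcription factor PRRX1. The labels call TGFb-treated MDCK-II cells partial EMT, TGFb-treated MDCK-NBL2 cells full EMT, treated MDCK-NBL2 cells with siPRRX1 partial EMT, and untreated cells epithelial. Each of the 8 groups had 3 libraries. Total counts ran from 7633467 to 23297302 in MDCK-II at day 0, from 8019068 to 27123727 in untreated MDCK-II at day 4 and from 8991167 to 27500500 in treated MDCK-II. In MDCK-NBL2 they ran from 6783222 to 27066739 at day 0, from 8021850 to 27567296 untreated at day 4 and from 6134929 to 9413761 with TGFb. With siCTR they ran from 7202327 to 26655390 and with siPRRX1 from 7349447 to 22172939. Below, levels are counts per 1000000 (CPM) as mean ± SD with n = 3, and log2 fold changes carry ± SE, derived from the F statistic. Each gene's spread is estimated over all 24 libraries. A library far from its group can therefore widen the SE of comparisons that do not use it.

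One library stood far apart from its group. On a principal component that held 60.8% of the variance, the library labelled MDCK-NBL2 untreated day 4 replicate 2 lay at -46.5, with replicates 1 and 3 of its group at 10.5 and 28.2 and the treated libraries of that line at -78.8, -70.9 and -67.1. TGFBI, a secreted matrix protein induced by TGFb and chosen here after its values were seen, was at 1580 CPM in it against 0.325 and 0.229 in replicates 1 and 3 and 9520, 7800 and 7490 with TGFb. COL1A1, a chain of type I collagen chosen in the same way, was at 596 CPM in it and listed at 0 in the other replicates of that group. MKI67, a marker of dividing cells and here also chosen after its values were seen, was at 35.3 CPM in it against 161 and 435 in the others. The number of genes changed in each comparison that uses this group, and some other values, are therefore also given without this library. A second library, MDCK-NBL2 day 0 replicate 1, carried genes otherwise seen in MDCK-II at a median of 9.69% of their MDCK-II level, while the upper quartile was at most 3.53% in any other MDCK-NBL2 library.

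**Figure D1:**
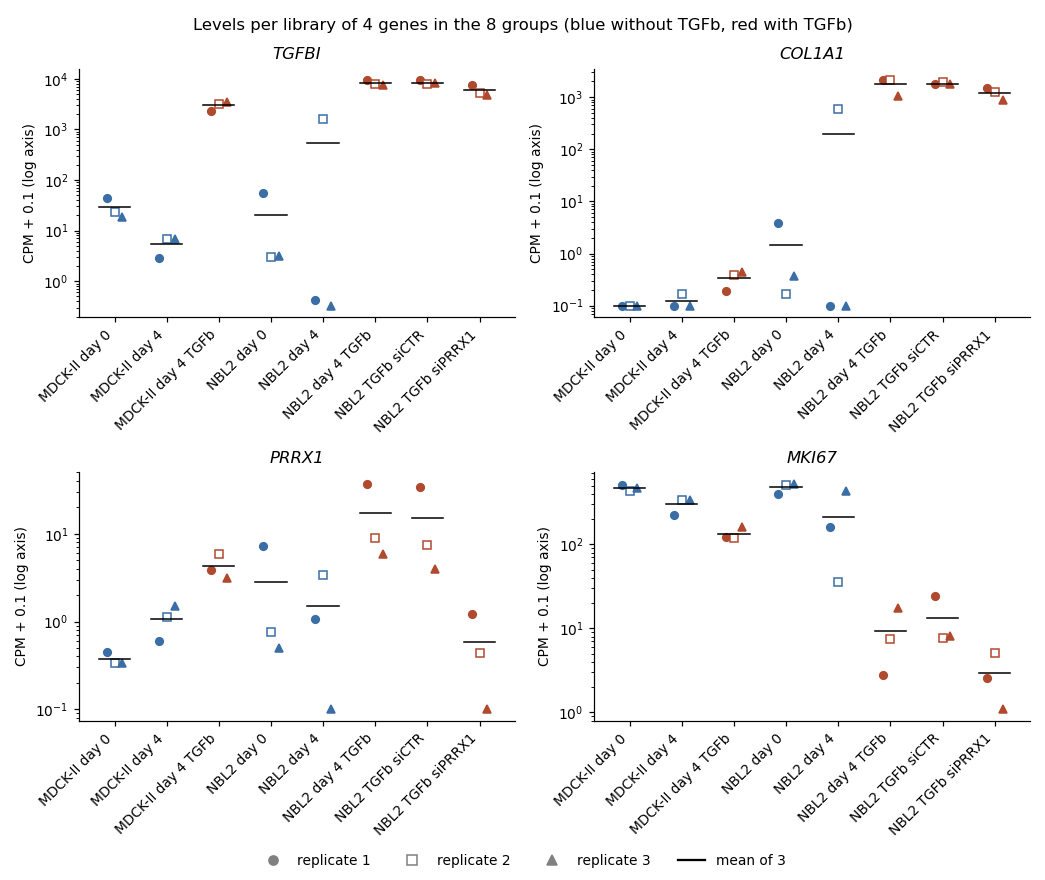
Levels of TGFBI, COL1A1, PRRX1 and MKI67 in each of the 24 libraries, in CPM plus 0.1 on a log axis, by group; blue points are libraries without TGFb, red points libraries with TGFb, and lines the mean of 3. For TGFBI and COL1A1, replicate 2 of untreated MDCK-NBL2 at day 4 lies closer to the treated libraries of that line than to its own group.

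In MDCK-II, where the labels name a partial transition, TGFb raised genes of the matrix, of matrix proteolysis and of Wnt signalling. TGFBI rose from 5.43 ± 2.28 to 3030 ± 589 CPM, a log2 fold change of 9.12 ± 2.09 (adjusted p = 0.0056). The collagenase MMP13 rose by 8.49 ± 1.28 (adjusted p = 0.00027) and the Wnt ligand WNT5B by 7.72 ± 1.16 (adjusted p = 0.00027). KRT27, a keratin, had no count in the untreated group and was at least 319-fold higher with TGFb (adjusted p = 0.0045). SLC22A2, a renal transporter of organic cations, was higher at a count ratio of 572 with a 95% counting interval of 102 to 22600 (adjusted p = 0.0002). Among the falls, IDO1, which breaks down tryptophan, went from 238 ± 94.9 to 7.87 ± 5.71 CPM, a log2 fold change of -4.85 ± 0.76 (adjusted p = 0.00034). The surfactant protein SFTPD changed by -3.56 ± 0.49 (adjusted p = 0.00015), the RNA-editing deaminase APOBEC1 by -2.80 ± 0.52 (adjusted p = 0.003) and EVA1C by -2.64 ± 0.38 (adjusted p = 0.00021).

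Of the 8 tested EMT transcription factors, 4 rose in MDCK-II and none fell (4 adjusted over the list alone). ZEB1, a repressor of epithelial genes, rose from 0.939 ± 0.377 to 10.1 ± 3.11 CPM, by 3.41 ± 0.82 (adjusted p = 0.0072), and SNAI1, another such repressor, from 4.96 ± 2.75 to 12.2 ± 2.24 CPM, by 1.27 ± 0.34 (adjusted p = 0.013). Without treated replicate 2 the SNAI1 change was 1.10 (adjusted p = 0.071). ZEB2 was at a count ratio of 54.5 with a 95% counting interval of 9.34 to 2200 (adjusted p = 0.035). Its adjusted p was 0.051 without treated replicate 1, 0.12 without treated replicate 2, and 0.051, 0.15 and 0.081 without untreated replicates 1, 2 and 3. TCF3 rose by 0.47 ± 0.14 (adjusted p = 0.021), with an adjusted p of 0.075 without treated replicate 1 and of 0.094 and 0.092 without untreated replicates 2 and 3. PRRX1 was at 0.972 ± 0.443 CPM untreated and 4.22 ± 1.46 with TGFb (2.18 ± 1.08, adjusted p = 0.15), and SNAI2 at 1.38 ± 0.65 (adjusted p = 0.13, or 0.034 without the doubted MDCK-NBL2 library). In the fit of these groups alone with a replicate block, PRRX1 was called at 2.24 (adjusted p = 0.0099) and SNAI2 at 1.63 (adjusted p = 0.011). The camera test of the list gave an adjusted p of 0.019, and 0.33 with an estimated correlation. It gave 0.059 without the doubted library.

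Epithelial genes moved in both directions. Of 30 tested adhesion and junction genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone): the adhesion molecule NECTIN1 rose by 1.19 ± 0.21 and the desmosome protein DSP by 0.93 ± 0.24, while the tight junction protein CGN changed by -1.17 ± 0.26 (adjusted p = 0.00099, 0.011 and 0.0044). The list did not pass (adjusted p = 0.51). Of 22 epithelial regulators and keratins, 2 rose and 6 fell (4 and 9 adjusted over the list alone), with ESRP1, a regulator of epithelial splicing, at -0.88 ± 0.14 and MAL2, a protein of apical transport, at -1.67 ± 0.30 (adjusted p = 0.0004 and 0.00099). This list passed at an adjusted p of 0.042, with 0.55 with an estimated correlation, 0.052 with a replicate block and 0.053 without the doubted library. E-cadherin (CDH1), the main adhesion molecule of epithelia and chosen here after its values were seen, was at 1100 ± 96 CPM untreated and 972 ± 57.3 with TGFb (adjusted p = 0.474).

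Mesenchymal and matrix lists rose in MDCK-II. Of 20 mesenchymal cytoskeleton and adhesion genes, 8 rose (10 up and 1 down adjusted over the list alone), among them the actin-binding CNN2 by 5.54 ± 0.87 (adjusted p = 0.00035) and the myosin light chain MYL9 by 4.12 ± 0.99 (adjusted p = 0.0073). Of 20 collagens, 7 rose (7 adjusted over the list alone), with COL12A1 from 3.73 ± 0.993 to 439 ± 72.3 CPM (adjusted p = 0.00015) and COL5A1 from 49.4 ± 24.9 to 350 ± 46.1 CPM (adjusted p = 9.2e-05). Of 30 matrix glycoproteins and proteoglycans, 15 rose (17 adjusted over the list alone), with the proteoglycan VCAN from 16.6 ± 4.47 to 220 ± 26.2 CPM (adjusted p = 3.1e-05). Among 36 matrix proteases, inhibitors and crosslinkers, 13 rose and 1 fell (16 and 2 adjusted over the list alone), with P4HA2, which hydroxylates collagen, at 1.44 ± 0.17 and BMP1, which trims procollagens, at 3.01 ± 0.53 (adjusted p = 2.9e-05 and 0.00088). Among 15 integrins, the cell receptors for matrix, 9 rose and 1 fell (9 and 2 adjusted over the list alone), with ITGA5 at 4.16 ± 0.74 and ITGB6 at 2.86 ± 0.51 (adjusted p = 0.00099 and 0.001). The 5 lists passed at adjusted p-values of 0.00023, 4.1e-06, 2.5e-10, 0.00023 and 7.2e-05 in this order, and gave adjusted p-values of 0.34, 0.32, 0.18, 0.36 and 0.18 with an estimated correlation. The median log2 fold changes were 1.08, 1.15, 1.28, 0.85 and 0.93, where genes of few counts set at their bound gave 1.25 for glycoproteins and 0.66 for proteases.

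Signalling and stress lists also moved in MDCK-II. Of 26 TGF-beta pathway genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone), with the ligands BMP4 at 2.35 ± 0.21 and TGFB2 at 2.24 ± 0.22 and the feedback inhibitor PMEPA1 at 2.97 ± 0.40 (adjusted p = 2.4e-06, 4.2e-06 and 0.00012). Of 14 Wnt genes, 7 rose and 2 fell (8 and 3 adjusted over the list alone), with the ligands WNT7B at 2.55 ± 0.39 and WNT5A at 5.65 ± 0.91 (adjusted p = 0.0003 and 0.00043). Of 19 YAP and TEAD targets, 10 rose (10 adjusted over the list alone), with AMOTL2, a brake on YAP, at 1.32 ± 0.24 (adjusted p = 0.001). Of 31 cytokine and NF-kB genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with the chemokine CX3CL1 at 1.31 ± 0.14 and the cytokine IL1A at 4.60 ± 1.05 (adjusted p = 1.5e-05 and 0.0053). Of 31 interferon response genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). Untreated replicate 1 differed from untreated replicates 2 and 3 by a median log2 of 1.09 for interferon response genes and of -0.63 for cell cycle genes. Of 20 ATF4 stress genes, 7 fell (1 up and 11 down adjusted over the list alone), with ATF5 at -2.43 ± 0.44 and DDIT3 at -1.51 ± 0.31 (adjusted p = 0.001 and 0.0027). The cell cycle list had 5 of 39 genes down, none of them when adjusted over the list alone, and 30 down without the doubted library. These lists passed, in this order, at adjusted p-values of 6.6e-13, 0.0075, 1.5e-05, 0.018, 0.016, 0.00023 and 3.3e-06, against 0.12, 0.12, 0.18, 0.5, 0.65, 0.34 and 0.5 with an estimated correlation.

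The other lists did not pass in MDCK-II. CDK inhibitors and p53 targets had 3 up and 1 down of 15 (adjusted p = 0.27), with CDKN1A, a brake on the cell cycle, at 1.83 ± 0.41 (adjusted p = 0.0049). Renal tubule genes had 5 up and 3 down of 25 (adjusted p = 0.35), with CA12 and the ion transporter SLC12A2 up by 3.51 ± 0.41 and 1.66 ± 0.24 (adjusted p = 2.6e-05 and 0.00019). Cholesterol synthesis (adjusted p = 0.81) and hypoxia genes (adjusted p = 0.45) had no member called, although the blocked fit of these groups alone called INSIG1 at 0.86, SLC16A3 at -1.04 and HK2 at -0.71 (adjusted p = 0.0074, 0.0045 and 0.0061). Of the marker lists for other cell types, 2 of 5 fibroblast markers rose (adjusted p = 0.12), among them PDGFRA, a growth factor receptor, by 3.51 ± 0.72 (adjusted p = 0.0027), 1 of 5 endothelial markers rose (adjusted p = 0.16), FLT1 by 1.56 ± 0.21 (adjusted p = 0.00012), and no leukocyte marker was called (adjusted p = 0.98). The endothelial marker KDR was called at 1.14 with the block (adjusted p = 0.011).

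In total 2626 of 12466 tested genes changed with TGFb in MDCK-II, 1471 up and 1155 down, and 1091 by at least 2-fold. A fit of these groups alone with a replicate block gave 3327 genes, and the block over all libraries 2822. The block in these groups alone also called 6 named genes that the fit of all libraries did not. The count was 1257 without treated replicate 2, 1526 without treated replicate 3 and 1690 without untreated replicate 3, and 3862 without the doubted MDCK-NBL2 library, of which 2625 were among the 2626. Of 87 named genes called, 61 kept their call whichever library of the groups compared was left out. Between 8 and 22 calls ended per library, at adjusted p-values of 0.05 to 0.28.

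In MDCK-NBL2, where the labels name a full transition, the largest rises named by the rule included a collagen and transporters, and the largest falls a mucin and a protease. COL3A1, a fibrillar collagen of connective tissue, was higher at a count ratio of 678 with a 95% counting interval of 231 to 3300 (adjusted p = 0.0027). The sodium-calcium exchanger SLC8A3 rose from 0.394 ± 0.683 to 86.3 ± 34.6 CPM, by 7.40 ± 0.83 (adjusted p = 7.3e-05). The glutamate transporter SLC1A1 rose by 7.01 ± 0.97 (adjusted p = 4.5e-05) and DYSF, a membrane repair protein, by 6.10 ± 0.93 (adjusted p = 8.9e-05). STMND1 rose by 7.0 and GASK1B by 6.21. SLC8A3, STMND1 and GASK1B had no untreated count without the doubted library, and were then at least 901-fold, at least 185-fold and at least 412-fold higher. The protease TMPRSS2 and the secreted protein LRG1 had no count with TGFb and were at least 128-fold and at least 74.8-fold lower (adjusted p = 0.0013 and 0.00015). The growth factor carrier FGFBP1 was lower at a count ratio of 162 with a 95% counting interval of 55.2 to 785 (adjusted p = 0.0002). The mucin MUC5B was at least 866-fold lower (adjusted p = 0.0078), with an adjusted p of 0.073 without untreated replicate 1. The sulfotransferase CHST4 changed by -7.93 ± 1.34 (adjusted p = 0.00018); without treated replicate 3 it had no count with TGFb and was at least 234-fold lower.

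PRRX1 was at 0.975, 3.25 and 0 CPM in untreated and 37.2, 8.89 and 5.71 CPM in treated MDCK-NBL2 replicates 1, 2 and 3. It rose by 3.41 ± 1.02 (adjusted p = 0.011), by 4.69 (adjusted p = 0.0038) without the doubted library, and was at 2.21 (adjusted p = 0.1) without treated replicate 1. Among the 8 tested EMT transcription factors, 3 rose and 1 fell (3 and 1 adjusted over the list alone). In the fit without the doubted library, which tested 9 of these factors, 5 rose and 1 fell. SNAI2 rose from 22.9 ± 26.8 to 133 ± 21.9 CPM, by 2.51 ± 0.67 (adjusted p = 0.0056), and by 4.20 without the doubted library. ZEB1 rose by 3.18 ± 0.84 (adjusted p = 0.0051; 4.86 without it). ZEB2 was at 1.81 (adjusted p = 0.14), and without that library at a count ratio of 76.4 with a 95% counting interval of 13 to 3080 (adjusted p = 0.0012). SOX9 fell by 0.98 on the log2 scale (adjusted p = 0.02), with -0.41 (adjusted p = 0.27) without untreated replicate 1 and -0.78 (adjusted p = 0.096) without treated replicate 3. SNAI1 was at 25.5 ± 11.1 CPM untreated and 21.4 CPM treated (-0.26 ± 0.32, adjusted p = 0.54). The list did not pass (adjusted p = 0.35).

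Epithelial genes fell more often than they rose. Of 30 junction genes, 5 rose and 8 fell (5 and 8 adjusted over the list alone; list adjusted p = 0.35). EPCAM, an epithelial surface marker, went from 584 ± 70.4 to 238 ± 22.7 CPM, the claudin CLDN3 from 62.4 ± 10.5 to 14.7 ± 1.27 CPM and the tight junction protein TJP3 from 73.4 ± 16.6 to 19.9 ± 3.28 CPM (adjusted p = 0.00011, 0.00012 and 0.00038). E-cadherin (CDH1), chosen after its values were seen, was at 1340 ± 376 CPM untreated and 901 ± 36.1 CPM treated (adjusted p = 0.00749). Of 22 epithelial regulators and keratins, 1 rose and 12 fell (1 and 12 adjusted over the list alone), among them GRHL2, a factor that keeps epithelial identity, at -1.94 ± 0.31, KLF5 at -2.81 ± 0.37 and MAL2 at -2.02 ± 0.31 (adjusted p = 0.00011, 3.2e-05 and 9.2e-05). ELF3, an epithelial transcription factor, was at -2.53 ± 0.44 (adjusted p = 0.00022), or -1.51 without untreated replicate 1. The list passed at an adjusted p of 0.0024, and gave 0.52 with an estimated correlation. The intermediate filament gene VIM, a mesenchymal marker also chosen after its values were seen, was at 3110 ± 1360 CPM untreated and 3260 ± 248 CPM treated (adjusted p = 0.863).

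Matrix genes rose broadly in MDCK-NBL2, and more of them without the doubted library. Of 20 collagens, 14 rose (14 adjusted over the list alone), with COL14A1 at 4.31 ± 0.62 and COL5A1 at 1.65 ± 0.36 (adjusted p = 8.1e-05 and 0.0011), and COL6A1 at 2.45, or 3.81 without the doubted library. Of 30 glycoproteins and proteoglycans, 16 rose and 2 fell (19 and 2 adjusted over the list alone), with the laminin LAMC1 at 1.38 ± 0.16 and LTBP2 at 4.67 ± 0.64 up and FBLN1 at -1.24 ± 0.18 (adjusted p = 1.1e-05, 6.1e-05 and 5.4e-05). Of 36 proteases, inhibitors and crosslinkers, 17 rose and 4 fell (19 and 4 adjusted over the list alone), with the collagen crosslinking enzyme PLOD2 at 2.72 ± 0.48 and the protease inhibitors SERPINE2 at -2.24 ± 0.29 and TIMP1 at -4.04 ± 0.68 (adjusted p = 0.00026, 3.1e-05 and 0.00018). Of 15 integrins, 10 rose and 3 fell (10 and 3 adjusted over the list alone), with ITGA6 at 2.13 ± 0.29 and ITGA9 at -1.32 ± 0.21 (adjusted p = 3.8e-05 and 0.00011). Of 20 mesenchymal genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with the focal adhesion protein VCL at 1.5 ± 0.25 and MYL9 at 3.56 ± 0.76 (adjusted p = 0.00018 and 0.0011; MYL9 6.10 without the doubted library), and S100A4 at -2.62 ± 0.40. The 5 lists passed at adjusted p-values of 2.5e-05, 1.1e-05, 0.00081, 0.0064 and 0.0015 in this order, each against 0.52 with an estimated correlation. In the fit without the doubted library 18 collagens, 25 glycoproteins, 24 of 37 proteases then tested, 11 integrins and 14 mesenchymal genes rose.

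The cell cycle list moved as a block. Of 39 tested members 38 fell (38 adjusted over the list alone; adjusted p = 1.6e-17, with 0.52 with an estimated correlation), and 38 fell without the doubted library. The spindle protein TPX2 was at -3.30 ± 0.49, the mitotic cyclin CCNB2 at -5.10 ± 0.77 and the replication helicase MCM7 at -2.37 ± 0.36 (adjusted p = 7e-05, 8.1e-05 and 8.1e-05). In MKI67 the treated libraries lay at 2.69, 7.43 and 17.3 CPM. Of 26 TGF-beta pathway genes, 11 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.0064, with 0.52 with an estimated correlation), with the receptor ACVR1 at 0.93 ± 0.16 (adjusted p = 0.00025), and 18 rose without the doubted library. Of 20 ATF4 stress genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone; adjusted p = 0.013, with 0.66 with an estimated correlation and 0.059 without the doubted library), with CTH, an enzyme of cysteine synthesis, at -2.47 ± 0.43 and the stress factor CEBPB at -1.62 ± 0.24 (adjusted p = 0.00025 and 7.1e-05).

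Interferon response genes fell in 13 of 31 and rose in 1 (14 and 1 adjusted over the list alone), with the antiviral genes HERC6 at -1.63 ± 0.30, MX1 at -4.11 ± 0.95 and IFI35 at -2.57 ± 0.60 (adjusted p = 0.00036, 0.0019 and 0.0023). The list gave an adjusted p of 0.058, and without the doubted library 3 members rose and 3 fell (adjusted p = 0.84). Cytokine genes rose in 7 and fell in 9 of 31 (8 and 9 adjusted over the list alone; list adjusted p = 0.59), with the adhesion receptor ICAM1 at 2.23 ± 0.40 and PTGES, which makes prostaglandin E, at -3.41 ± 0.66 (adjusted p = 0.00032 and 0.00049). In the fit without the doubted library 12 of 32 cytokine genes rose and 9 fell (list adjusted p = 0.31). The lists of CDK inhibitors and p53 targets (adjusted p = 0.63), renal tubule genes (adjusted p = 0.16), YAP targets (adjusted p = 0.34), Wnt genes (adjusted p = 0.5), cholesterol synthesis (adjusted p = 0.85) and hypoxia (adjusted p = 0.22) did not pass. Their members included WNK1, a kinase that controls ion transport, up by 1.33 ± 0.12, RRM2B, which makes DNA precursors, up by 1.53 ± 0.22, and TCF7, a Wnt effector, at -1.09 ± 0.16 (adjusted p = 1.7e-06, 5.6e-05 and 6.7e-05). Of the marker lists, 2 of 5 fibroblast markers rose (adjusted p = 0.11), COL14A1 and LUM, which also stand in the matrix lists, with LUM at least 42.1-fold higher (adjusted p = 0.0026). Endothelial markers had 2 up and 3 down of 5 (adjusted p = 0.91), and 1 of 4 leukocyte markers rose (adjusted p = 0.63), the actin bundler LCP1 by 3.48 ± 1.00 (adjusted p = 0.0097).

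TGFb changed 5525 of 12466 genes in MDCK-NBL2, 2612 up and 2913 down, and 2291 by at least 2-fold. Without the doubted library 6890 changed, 5328 of them called in the same direction as before. With only these groups in the model 510 genes passed. Of 110 named genes called, 99 kept their call whichever library of the groups compared was left out, and between 3 and 7 calls ended per library, at adjusted p-values of 0.052 to 0.27. With only these groups in the model, 42 of the 105 named calls that could be tested were kept.

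Both lines shared much of the response. There were 920 genes higher in both, where 308.2 would be expected if the calls were independent, and 760 lower in both against 269.9. These made up 62.5% of the rises and 65.8% of the falls in MDCK-II. Without the doubted library 1571 and 1396 were shared, against 548.2 and 509.4 expected. Across single libraries of these groups left out the counts ran from 498 to 1571 higher and from 285 to 1396 lower. Both low ends came without treated MDCK-II replicate 2, where 164.2 and 101.3 would be expected. The 12466 log2 fold changes correlated at r = 0.56 and rho = 0.64 across genes, which are not independent replicates. The actin-linked PDLIM3 was higher in both, with a count ratio of 384 (95% counting interval 68.4 to 15200) in MDCK-II and a log2 fold change of 4.93 in MDCK-NBL2, or a count ratio of 362 (64.3 to 14400) without the doubted library. HMGB2, a chromatin protein, was at -2.05 ± 0.52 and -5.55 ± 0.67, TMEM171 at -3.33 ± 0.50 and -3.72 ± 0.51, and TIMP1 at -4.59 ± 0.86 and -4.04 ± 0.68. Only 46 genes were called in opposite directions, and the difference was called for 46 of them.

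**Figure D2:**
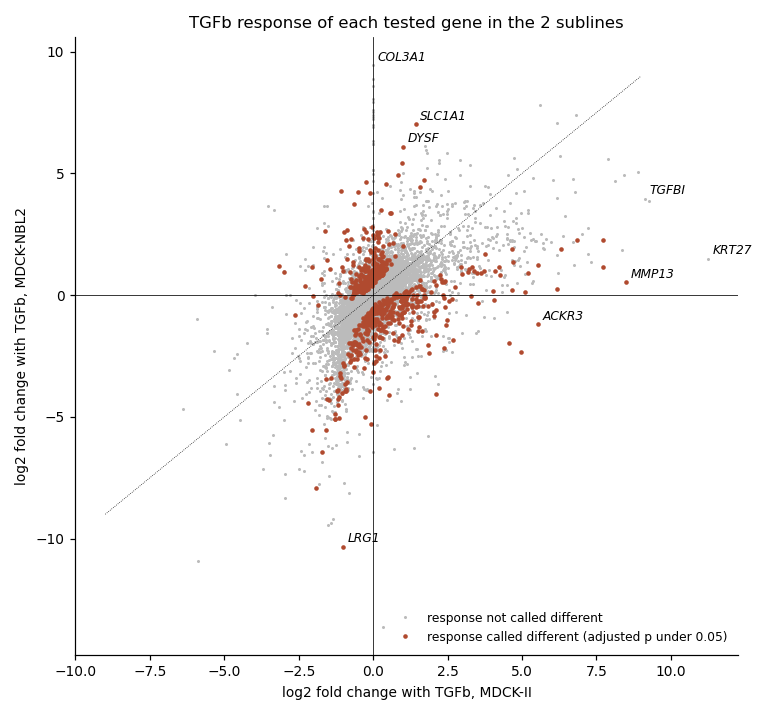
Log2 fold change with TGFb in MDCK-II (x axis) and MDCK-NBL2 (y axis) for 12466 genes; red points are the 711 genes whose response was called different between the lines, and the dotted diagonal marks equal change. Across genes the fold changes of the lines correlated at r = 0.56.

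The difference between the responses was tested directly, since the labels give the lines a different degree of transition. Genes with a larger rise in MDCK-NBL2 included SLC1A1 at 5.59 ± 1.17, DYSF at 5.08 ± 1.13 and FST, which binds activin, at 4.37 ± 0.94 (adjusted p = 0.01, 0.014 and 0.012). Of 30 junction genes, CXADR was called higher in the MDCK-NBL2 response (adjusted p = 0.043) and TJP3 at -2.71 ± 0.48 and EPCAM at -1.24 ± 0.29 lower, and of 22 epithelial regulators only the splicing regulator ESRP2 was called with all libraries, at -0.84 ± 0.17 (adjusted p = 0.0043, 0.017 and 0.01). Without the doubted library 17 more named genes were called different. MMP13 was at -7.97 ± 1.5 (adjusted p = 0.0063), and at -4.15 (adjusted p = 0.033) without the doubted library; its direction turned, at 3.07 (adjusted p = 0.87), without 3 day 4 untreated libraries. The ligands BMP4 at -2.36 ± 0.29, TGFB2 at -1.40 ± 0.30 and WNT7B at -2.80 ± 0.53, the chemokine CX3CL1 at -1.79 ± 0.20 and the matrix proteins VCAN at -2.75 ± 0.57 and FBLN1 at -1.29 ± 0.24 rose less or fell more in MDCK-NBL2 (adjusted p = 0.0003, 0.012, 0.0063, 0.00013, 0.01 and 0.006). None of the 8 EMT transcription factors was called different (1 lower adjusted over the list alone; list adjusted p = 0.66). PRRX1 was at 1.23 ± 1.46 (adjusted p = 0.68) and SNAI1 at -1.53 ± 0.47 (adjusted p = 0.058), with adjusted p-values of 0.013 without the doubted library, 0.021 without untreated MDCK-II replicate 2 and 0.037 without untreated MDCK-NBL2 replicate 3. SNAI2 was at 1.12 (adjusted p = 0.51), and at 2.81 (adjusted p = 0.013) without it.

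Among the lists, the cell cycle stood lower in the MDCK-NBL2 response, with 5 of 39 members called (32 adjusted over the list alone; 36 called without the doubted library), among them CCNB2 at -3.81 (adjusted p = 0.027, with 0.08 and 0.072 without treated MDCK-NBL2 replicates 1 and 2). Of 31 interferon genes 7 were lower (14 adjusted over the list alone), of 26 TGF-beta pathway genes 1 was higher and 7 were lower (1 and 9), of 14 Wnt genes 4 were lower (7 adjusted over the list alone), among them the Wnt feedback inhibitors AXIN2 at -2.35 ± 0.48 and NOTUM at -1.71 ± 0.39 (adjusted p = 0.01 and 0.016), and of 19 YAP targets 3 were lower (6 adjusted over the list alone). These 5 lists passed at adjusted p-values of 1.1e-13, 9.1e-07, 0.0021, 0.00012 and 0.01, and gave 0.82, 0.82, 0.82, 0.018 and 0.82 with an estimated correlation. Without the doubted library the interferon, TGF-beta and YAP lists gave 0.066, 0.44 and 0.4, the Wnt list 0.014 (adjusted p = 0.083 with an estimated correlation) and the cell cycle list 3.9e-30 (0.26 with an estimated correlation). In that fit the mesenchymal list (8 up and 2 down) and the protease list (11 up and 4 down of 37) passed at 0.035, against 0.86 and 0.72 with all libraries, and both gave 1.0 in that fit with an estimated correlation. The lists of junctions (adjusted p = 0.12), epithelial regulators (0.1), collagens (0.8), glycoproteins (0.12), integrins (0.86), cytokines (0.34), CDK inhibitors (0.8), renal genes (0.66), cholesterol (0.8), ATF4 (0.86), hypoxia (0.66), fibroblast (0.66), endothelial (0.66) and leukocyte markers (0.8) did not pass.

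The responses differed in 711 genes, with a larger rise or smaller fall in MDCK-NBL2 for 314 and a smaller rise or larger fall for 397, and 405 by at least 2-fold. Without the doubted library the count was 2653, of which 701 were called in the same direction as before. It was 867, 451 and 350 without untreated MDCK-II replicates 1, 2 and 3, 398, 353 and 506 without treated MDCK-II replicates 1, 2 and 3, 311, 415 and 411 without treated MDCK-NBL2 replicates 1, 2 and 3, and 48 with only these groups in the model. That model kept 8 of the 51 named calls. Of 51 named genes called, 22 kept their call whichever library of the groups compared was left out. The calls that ended numbered 25 without treated MDCK-NBL2 replicate 1 and 23 without untreated MDCK-II replicate 3, with adjusted p-values up to 0.13 and 0.1.

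**Figure D3:**
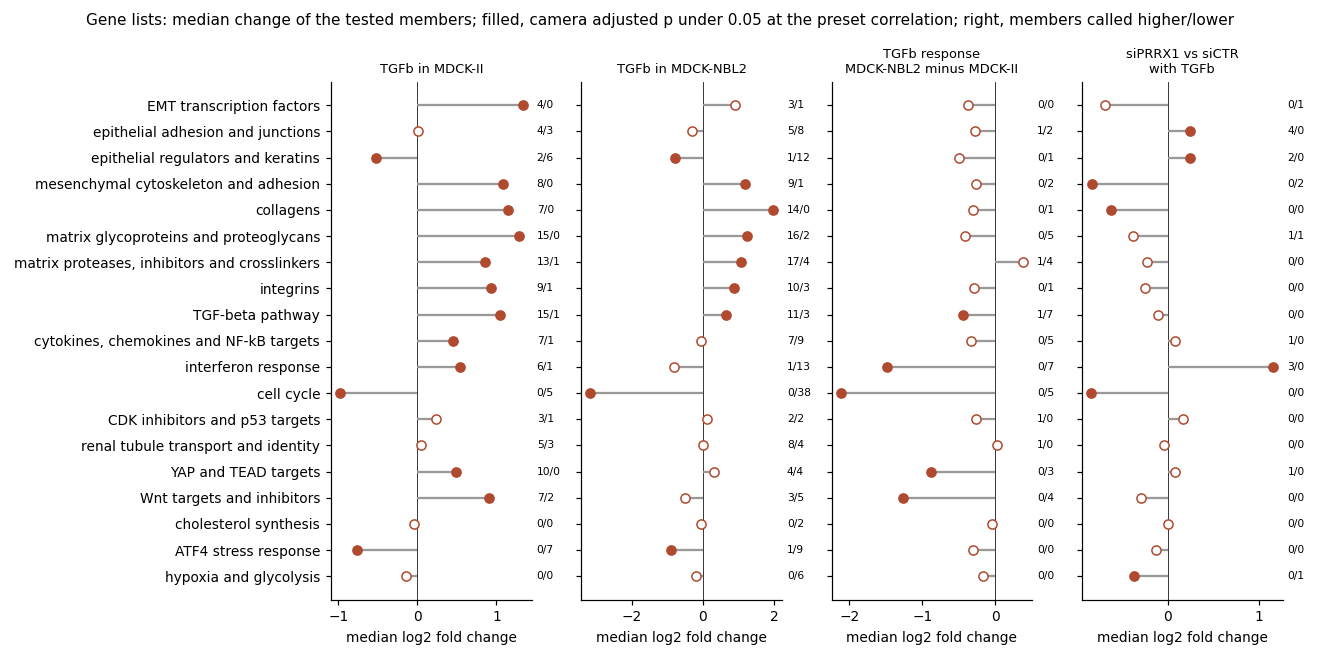
Median log2 fold change of each gene list except the marker lists of other cell types (x axis) in the 4 main comparisons, with filled points where the camera adjusted p was under 0.05 at the preset correlation and, at right, the numbers of members called higher and lower. The cell cycle list lies lowest in treated MDCK-NBL2, with 38 of 39 members lower.

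The knockdown asked what PRRX1 contributes in treated MDCK-NBL2 cells. PRRX1 was at 33.9, 7.35 and 3.88 CPM in siCTR and 1.11, 0.339 and 0 CPM in siPRRX1 replicates 1, 2 and 3, and so lower in 3 of 3 pairs. It changed by -4.64 ± 1.17 (adjusted p = 0.043), and its spread between libraries was wide: the adjusted p was 0.3, 0.056 and 0.059 without siCTR replicates 1, 2 and 3 and 0.072, 0.17 and 0.21 without siPRRX1 replicates 1, 2 and 3. Of the other EMT transcription factors, SNAI2 was at 89.4 ± 15.3 CPM with siCTR and 35.0 ± 16.8 with siPRRX1 (-1.34 ± 0.65, adjusted p = 0.35), ZEB1 at -1.63 ± 0.76 (adjusted p = 0.32), ZEB2 at -1.24 (adjusted p = 0.61) and SNAI1 at -0.13 (adjusted p = 0.92). Only PRRX1 itself was called among the 8, and the list did not pass (adjusted p = 0.15). These values are without a replicate block, although the replicate numbers pair these libraries. A fit of these groups alone with the block kept the 27 named calls it could test and called 47 more named genes, among them SNAI2 at -1.37 (adjusted p = 0.00034) and ZEB1 at -1.66 (adjusted p = 0.0023), while SNAI1 was not called (adjusted p = 0.42).

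IFI6, an interferon-induced gene, was among the largest rises with siPRRX1; it had no count with siCTR and was at least 152-fold higher (adjusted p = 0.0031). IL1RL1, the receptor of the alarmin IL-33, rose from 0.401 ± 0.447 to 18.2 ± 11.9 CPM, by 4.93 ± 0.80 (adjusted p = 0.0026). EHD2, which coats membrane pits, went from 187 ± 4.69 to 45.2 ± 13.9 CPM, by -2.04 ± 0.26 (adjusted p = 0.00028), and C1QL1 from 16.5 ± 7.38 to 1.73 ± 0.383 CPM, by -3.22 ± 0.54 (adjusted p = 0.0031). The desmosome cadherin DSG2 rose from 395 ± 22.4 to 594 ± 65.5 CPM (0.59 ± 0.10, adjusted p = 0.0028). PAQR5 rose by 1.17 ± 0.21 and the junction protein IGSF5 by 1.49 ± 0.25 (adjusted p = 0.0046 and 0.003). With all libraries the smooth muscle actin ACTG2 was at -2.83 ± 0.58, the gap junction protein GJA1 at -2.20 ± 0.49, VCAN at -1.92 ± 0.40, E-cadherin (CDH1) at 0.68 ± 0.16, the tight junction protein OCLN at 0.58 ± 0.14, CLDN3 at 1.29 ± 0.33 and IFIT1, an antiviral gene, at 4.99 ± 1.20 (adjusted p = 0.019, 0.036, 0.017, 0.033, 0.033, 0.047 and 0.034). Without siPRRX1 replicate 3 their adjusted p-values were 0.14, 0.21, 0.13, 0.21, 0.21, 0.18 and 0.18. The chemokine CXCL10 was at a count ratio of 32.7 with a 95% counting interval of 10.9 to 161 (adjusted p = 0.014), with 0.098 without siPRRX1 replicate 3, 0.14 without siCTR replicate 1 and 0.067 without siCTR replicate 3. Of 29 named genes called, 7 kept their call whichever library of the groups compared was left out; calls ended for 21, 10 and 20 genes without siCTR replicates 1, 2 and 3 and for 5, 18 and 22 genes without siPRRX1 replicates 1, 2 and 3, at adjusted p-values of 0.05 to 0.3.

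**Figure D4:**
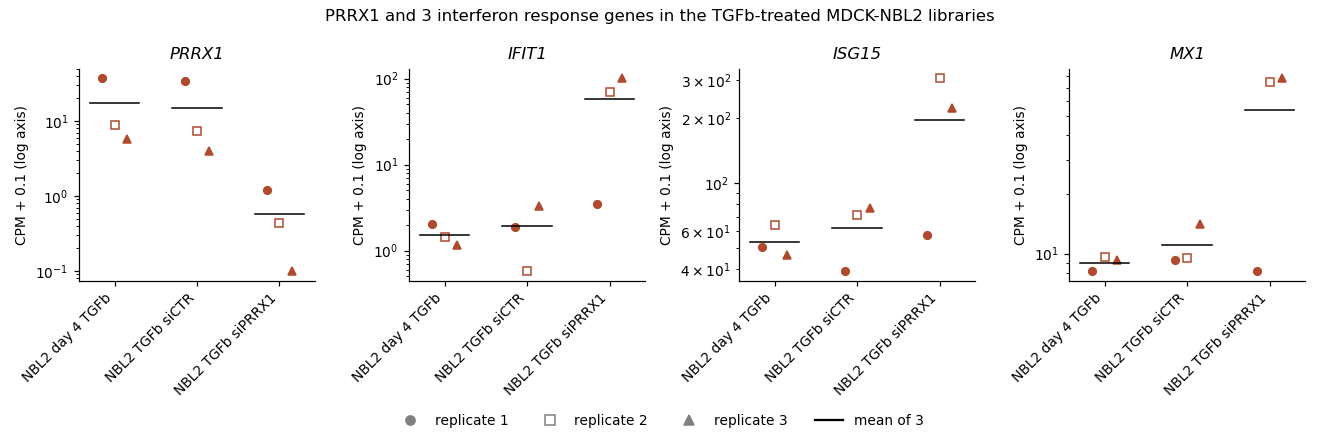
Levels of PRRX1, IFIT1, ISG15 and MX1 in CPM in each TGFb-treated MDCK-NBL2 library without siRNA, with siCTR and with siPRRX1. IFIT1 lies at 3.38 CPM in siPRRX1 replicate 1 and at 70.3 and 101 CPM in replicates 2 and 3.

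Of 31 interferon response genes, 3 rose with siPRRX1 (15 adjusted over the list alone), and the list passed at an adjusted p of 1.1e-13, with 0.5 with an estimated correlation. The list median was 0.55 between libraries of replicate number 1 and 1.32 and 1.10 between those of numbers 2 and 3, which belong to another library number series. Junction genes rose in 4 of 30 (8 up and 2 down adjusted over the list alone) and epithelial regulators in 2 of 22 (3 adjusted over the list alone), with list adjusted p-values of 0.0017 and 0.00028, against 0.5 and 0.5 with an estimated correlation. The junction medians by replicate number were 0.14, 0.24 and 0.42. Mesenchymal genes fell in 2 of 20, FHL1 and FHL2 (9 adjusted over the list alone), with a list adjusted p of 4.3e-07 and 0.5 with an estimated correlation, and medians of -0.80, -0.73 and -0.91 by replicate number. Of 20 collagens none was called, among them COL3A1 at -4.02 ± 1.36 (adjusted p = 0.17, with 0.00038 with a replicate block over all libraries and 3.3e-05 with the block in these groups alone), while the list passed at 0.015 (adjusted p = 0.68 with an estimated correlation). The cell cycle list had no member called and passed at 2.4e-08 (adjusted p = 0.68 with an estimated correlation), with medians of -1.30, -0.23 and -0.67; with the block in these groups alone MKI67 was called at -2.35 (adjusted p = 0.0068). Of 25 hypoxia and glycolysis genes, GAPDH fell by 0.57 (2 down adjusted over the list alone), and the list gave 0.0079 (adjusted p = 0.68 with an estimated correlation) with medians of 0.04, -0.50 and -0.45. The calls of FHL1, FHL2 and GAPDH ended without siPRRX1 replicate 3 (adjusted p = 0.24, 0.2 and 0.17) and without other single libraries. These counts of members called are with all libraries. Without the doubted untreated library 19 more named genes were called in this comparison. The lists of glycoproteins (adjusted p = 0.23), proteases (0.15), integrins (0.42), TGF-beta pathway (0.79), cytokines (0.39), CDK inhibitors (0.3), renal genes (0.98), YAP targets (0.17), Wnt genes (0.15), cholesterol (0.98), ATF4 (0.71), fibroblast (0.99), endothelial (0.41) and leukocyte markers (0.98) did not pass.

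With siPRRX1, 249 genes changed, 101 up and 148 down, and 81 by at least 2-fold. A replicate block over all libraries gave 263, and a fit of these groups alone gave 1159, or 2528 with the block. The count was 655 without the doubted untreated library, which included the 249, 98, 139 and 75 without siCTR replicates 1, 2 and 3, and 114 and 54 without siPRRX1 replicates 2 and 3. DESeq2 gave 472 and the fit without a filter 163. Of the 148 genes lower with siPRRX1, 67 were among those TGFb had raised in MDCK-NBL2, where 31 would be expected, and of the 101 higher, 39 were among those TGFb had lowered, against 23.6. In the same direction as TGFb were 15 against 21.2 and 15 against 34.6. Across genes the log2 fold changes of TGFb in MDCK-NBL2 and of siPRRX1 correlated at r = -0.14 and rho = -0.19. Besides PRRX1, the 67 included C1QL1, EHD2 and ACTG2, raised by TGFb by 5.84 ± 0.64, 0.88 ± 0.25 and 5.14 ± 0.69; without the doubted library the count ratios of C1QL1 and ACTG2 were 282 (95% counting interval 77.6 to 2340) and 784 (140 to 31000). PAQR5 and IGSF5, at -2.62 ± 0.22 and -1.44 ± 0.25 with TGFb, were among the 39. Without siPRRX1 replicate 3 the counts were 22 and 5, against 8.2 and 2.9 expected. Without the doubted library they were 237 and 96, against 110.3 and 68.7 expected.

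The control siRNA tests what transfection alone does. Comparing siCTR with no siRNA in treated MDCK-NBL2, edgeR called no gene and DESeq2 called none. Of 12466 genes tested, 212 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone would give. The spread in this fit is estimated over all 24 libraries. A fit of these groups alone called 0 genes, with 447 of 11050 under 0.05. The absence of calls therefore does not show that transfection had no effect. PRRX1 was at 15 ± 16.4 and 17.3 ± 17.3 CPM (-0.12 ± 0.90, adjusted p = 1.0) and SNAI1 at -0.26 (adjusted p = 1.0). The cell cycle list had a median of 0.32 and an adjusted p of 8.2e-06 with none of its members called, and 0.98 with an estimated correlation.

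Untreated cells also changed between day 0 and day 4. In MDCK-II, genes of amino acid stress and sterol synthesis rose: FGF21, a stress hormone, from 0.585 ± 0.306 to 21.0 ± 3.48 CPM, DDIT4, a stress brake on mTOR, from 9.19 ± 2.69 to 204 ± 84.9 CPM and CHAC1, which degrades glutathione, from 8.91 ± 1.03 to 96.7 ± 20.4 CPM (adjusted p = 0.0039, 0.0013 and 0.00032). The xenobiotic enzyme CYP1A1 went from 228 ± 153 to 0.547 ± 0.484 CPM, the chemokine receptor CXCR4 from 22.3 ± 9.68 to 0.46 ± 0.348 CPM and VCAN from 204 ± 20.9 to 16.6 ± 4.47 CPM (adjusted p = 0.00054, 0.00039 and 0.00011). PRRX1 (1.77 ± 1.44) and SNAI1 (-0.58 ± 0.34) were not called (adjusted p = 0.45 and 0.29). ATF4 stress genes rose in 15 of 20 (16 adjusted over the list alone), cholesterol synthesis genes in 13 of 20 (16), interferon genes in 8 of 31 (17) and hypoxia genes in 6 of 25 (10), with VEGFA by 2.21 ± 0.44. Day 4 replicate 1 stood above replicates 2 and 3 by a median of 1.09 for the interferon and 0.68 for the hypoxia list. With it left out the interferon gene ISG15 went from 3.07 (adjusted p = 0.01) to 2.02 (adjusted p = 0.09) and VEGFA to 1.90 (adjusted p = 0.02). The ATF4, cholesterol, interferon and hypoxia lists passed at 3.2e-18, 1.7e-14, 6e-07 and 0.00013, against adjusted p-values of 0.078, 0.14, 0.59 and 0.59 with an estimated correlation. TGF-beta pathway genes fell in 6 of 26 (7 adjusted over the list alone), BMP4 by 1.48 on the log2 scale, at 9.3e-05 (adjusted p = 0.55 with an estimated correlation). Cell cycle genes passed as a list, lower, at 0.0014 with no member called and a median of -0.52. Glycoproteins passed lower at 0.025 with 3 of 30 called, Wnt genes lower at 0.025 with 2 of 14, and CDK inhibitors higher at 0.039 with 3 of 15 (0.054 without the doubted library). These 4 lists gave 0.8, 0.8, 0.14 and 0.59 with an estimated correlation. In all, 1223 genes changed, 718 up and 505 down. The count was 2075 without the doubted MDCK-NBL2 library, where 11 more named genes were called. It was 509, 532 and 589 without day 0 replicates 1, 2 and 3 and 604 without day 4 replicate 1. Of 44 named genes called, 23 kept their call whichever library of the groups compared was left out.

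In MDCK-NBL2 the interferon-induced ISG15 rose from 6.76 ± 4.78 to 179 ± 159 CPM between day 0 and day 4 (adjusted p = 0.0027), and IL1RL1 and CYP1A1 were lower by -4.18 ± 0.61 and -4.20 ± 0.98 (adjusted p = 0.0021 and 0.01). Interferon genes rose in 21 of 31 (23 adjusted over the list alone), among them PARP14 by 2.76 ± 0.39 and DTX3L by 2.30 ± 0.35, cholesterol synthesis genes in 14 of 20 (17), with SQLE by 1.11 ± 0.17, and ATF4 stress genes in 10 of 20 (10), with CHAC1 by 2.76 ± 0.47. These lists passed at 5.8e-16, 4.7e-09 and 5.2e-05, against adjusted p-values of 0.35, 0.35 and 0.58 with an estimated correlation. CDK inhibitors and p53 targets rose in 7 of 15 and fell in 1 (9 and 1), with SESN2, a stress sensor, by 2.07 ± 0.31, junction genes rose in 9 of 30 and fell in 2 (11 and 2), and epithelial regulators rose in 3 of 22, at 0.00052, 0.01 and 0.0027 (adjusted p = 0.35, 0.58 and 0.58 with an estimated correlation). Cell cycle genes fell in 4 of 39 (2 adjusted over the list alone; adjusted p = 7.9e-13, with 0.58 with an estimated correlation). In the fit without the doubted library 17 interferon, 10 cholesterol, 10 ATF4, 6 CDK inhibitor, 6 junction and 8 epithelial regulator genes rose and 2 cell cycle genes fell, and these lists passed. The mesenchymal, protease and integrin lists passed lower there (adjusted p = 0.00033, 0.042 and 0.047), against 0.5, 0.55 and 0.52 with an estimated correlation. The other lists named gave 0.5 to 0.55 with it. The hypoxia list, at 0.17 with all libraries, passed higher there at 0.042 (0.6 with an estimated correlation). PRRX1 was at -0.79 ± 1.01 (adjusted p = 0.59) and SNAI1 at 0.38 ± 0.32 (adjusted p = 0.39). The matrix protein THBS1 was called at 1.79 (adjusted p = 0.033), but was at -0.10 (adjusted p = 0.79) without the doubted library. In all, 2206 genes changed, 1550 up and 656 down, and 1832 without that library, 1189 of them called in the same direction as before. The count was 1265, 729 and 1130 without day 0 replicates 1, 2 and 3, 1023 and 5324 without day 4 replicates 1 and 3, and 0 by edgeR in a fit of these groups alone, where 1614 genes had an unadjusted p under 0.05 and DESeq2 with all groups gave 2707. Of 57 named genes called, 28 kept their call whichever library of the groups compared was left out. With only these groups in the model, 0 of the 54 named calls that could be tested were kept.

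Untreated, the lines themselves differed widely. At day 4, the adhesion molecule ALCAM, the collagen COL1A2 and the scaffold IQGAP2 had no count in MDCK-II and were at least 3740-fold, at least 2020-fold and at least 1230-fold higher in MDCK-NBL2, while the transcription factor GATA4 and APOBEC1 had none in MDCK-NBL2 and were at least 245-fold and at least 314-fold lower. These bounds pool the libraries of each group, the doubted library among them, and were not computed without it. At day 0, COL1A2 was at 68.3, 14.6 and 12.4 CPM in MDCK-NBL2 replicates 1, 2 and 3. SNAI1 was higher in MDCK-NBL2, at 25.5 ± 11.1 against 4.96 ± 2.75 CPM (2.33 ± 0.34, adjusted p = 2.4e-05), and PRRX1 was at 0.74 (adjusted p = 0.63). The claudin CLDN6 was at 3.91 ± 0.30 and the membrane protein PROM2 at 5.94 ± 0.40 (adjusted p = 7.7e-09 and 1.4e-09). Their lists had 8 of 30 junction genes higher and 2 lower (adjusted p = 0.11) and 11 of 22 epithelial regulators higher and 1 lower (adjusted p = 0.006), each with 0.66 with an estimated correlation. The TGFb receptor TGFBR1 was at 1.85 ± 0.20, and the kidney transcription factor PAX2 at -2.30 ± 0.21 (adjusted p = 8.3e-07 and 9.3e-08). TGF-beta pathway genes were higher in 19 of 26 and lower in 1 (13 and 3 without the doubted library), and Wnt genes higher in 11 of 14 and lower in 1, with AXIN2 at 3.16 ± 0.36 (adjusted p = 1.2e-06). These lists passed at 0.00017 and 0.00023 (adjusted p = 0.66 and 0.013 with an estimated correlation). The mesenchymal list had 12 of 20 higher at 0.0019, or 8 without the doubted library, and collagens had 9 of 20 higher and 1 lower at 0.026, or 0.063 without it, each with 0.66 with an estimated correlation. Glycoproteins had 16 of 30 higher at 0.0021, and proteases 16 of 36 higher and 3 lower at 0.02, or 0.21 without that library, each with 0.66 likewise. Lists that passed lower included cholesterol synthesis with 11 of 20 lower (adjusted p = 0.006), ATF4 stress genes with 9 of 20 lower (0.016) and renal tubule genes with 4 of 25 higher and 8 lower (0.02), each also with 0.66. Cell cycle genes passed as a list, lower, at 0.043 (median -0.42; adjusted p = 0.8 with an estimated correlation), with 1 of 39 higher and 1 lower, but its direction turned at 0.92 in the fit without the doubted library. The interferon list, at 0.12 with all libraries, passed lower in that fit at 0.007 (0.71 with an estimated correlation). In all, 4527 genes differed, 2615 higher in MDCK-NBL2 and 1912 lower, and 4294 without the doubted library, 3552 of them called in the same direction as before. With only these groups in the model the count was 1267.

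At day 0 3558 genes differed, 1839 higher in MDCK-NBL2 and 1719 lower. The doubted library is in neither group but enters the model, and without it 4271 differed, 3554 of them called in the same direction as before. The count was 3718 with a replicate block and 5261 with that block in a fit of these groups alone. ALCAM and the gap junction protein GJA1 were at least 1620-fold and at least 773-fold higher in MDCK-NBL2, and PDPN, a marker of podocytes and lymphatic vessels, was at a count ratio of 10100 with a 95% counting interval of 1810 to 399000. SFTPD was at -5.85 ± 0.60 (adjusted p = 5.5e-07), and the receptor ERBB4 at -5.72 and PLXNA4 at -5.59; without MDCK-NBL2 replicate 1 both had no count in that line and were at least 144-fold and at least 279-fold lower. SNAI1 was at 1.37 ± 0.33 (adjusted p = 0.0038), PRRX1 at 3.30 (adjusted p = 0.067; 1.08 with adjusted p = 0.66 without MDCK-NBL2 replicate 1, and 3.84 with adjusted p = 0.044 without its replicate 2), CLDN6 at 3.06, PROM2 at 4.69 and TGFBR1 at 2.06. Interferon genes were lower in 14 of 31 and higher in 1 (14 and 1 adjusted over the list alone), with the antigen transporter TAP1 at -2.66 ± 0.30, renal genes lower in 8 of 25 and higher in 2 (10 and 2), with CUBN, a receptor for protein uptake in the tubule, at -2.30 ± 0.22, and mesenchymal genes higher in 7 of 20 (9 up and 1 down adjusted over the list alone). These lists passed at 6.7e-05, 0.011 and 0.0053, each against an adjusted p of 1.0 with an estimated correlation. Wnt genes were higher in 7 of 14 and lower in 2 at 0.011 (adjusted p = 0.1 with an estimated correlation). Epithelial regulators were higher in 8 of 22 and lower in 2 at 0.037, and cholesterol genes lower in 9 of 20 at 0.035, both at 0.056 without the doubted library and 1.0 with an estimated correlation. Of 65 named genes called, 60 kept their call whichever library of the groups compared was left out, and of 69 at day 4, 65 kept it. With only the compared groups in the model, 64 of 64 named calls that could be tested were kept at day 0 and 52 of 68 at day 4.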

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

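The tests of the 3 patterns weighed here were chosen after the result was seen; the test of the difference between the lines and the counts of other splits of the libraries were not.

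A direct test of the difference between the TGFb responses of MDCK-NBL2 and MDCK-II singled out 711 genes. The largest differences named by the rule were larger rises in MDCK-NBL2 for SLC1A1 (5.59), DYSF (5.08), ABCA13 (4.91), FST (4.37), TGFBR3 (4.23) and HAPLN3 (4.15), on the log2 scale. In the other direction were LRG1 (-9.34), MMP13 (-7.97), ACKR3 (-6.72), SCGB1A1 (-6.17) and CHST4 (-6.02). The doubted library held 31 of the 32 untreated MDCK-NBL2 counts of HAPLN3, so 4.15 depends on it. MMP13 was at -4.15 (adjusted p = 0.033) without that library, and turned to 3.07 (adjusted p = 0.87) without 3 day 4 untreated libraries. Without another single library, ABCA13 was at 2.19 (adjusted p = 0.36, untreated MDCK-II replicate 1), and adjusted p-values reached 0.12 for TGFBR3 (treated MDCK-NBL2 replicate 1), 0.14 for LRG1 (treated MDCK-II replicate 2) and 0.13 for ACKR3 (untreated MDCK-NBL2 replicate 1). The same test passed at list level for the TGF-beta pathway (adjusted p = 0.0021), the interferon response (9.1e-07), the cell cycle (1.1e-13), YAP and TEAD targets (0.01) and Wnt genes (0.00012), of which the Wnt list passed with an estimated correlation, but not without the doubted library (adjusted p = 0.083). In 16 of 100 splits of these libraries, drawn from 200, as many genes or more than 711 were called. Of the 15 others as large, 11 leave the treatment labels of 1 line together and so hold the whole response of that line, and the other 4 hold part of each response. The splits therefore do not measure chance for a difference between responses, which they leave open. The highest other split called 6283 genes. It exchanges the treatment labels within 1 line and so adds both responses, which are largely shared. Its large count was therefore fixed in advance and tells nothing more about the samples.

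For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split called 2626 genes for TGFb in MDCK-II against 4 in the highest other, 5525 against 1347 in MDCK-NBL2, 249 against 0 for siPRRX1, 1223 against 1 for time in MDCK-II, 4527 against 3892 between the untreated lines at day 4 and 3558 against 0 at day 0, and was reached by 1 split in each, the real one. Where the numbers pair the libraries, the other splits that part as many pairs called 0 genes for TGFb in MDCK-II, for siPRRX1 and for the lines at day 0. For siCTR against no siRNA all 10 splits called 0 genes by edgeR, and DESeq2 called 0 in the real split. There 212 of 12466 genes had an unadjusted p under 0.05, a smaller share than the 0.05 of chance alone. For time in MDCK-NBL2, 2 of 10 splits were as large, with 2698 genes against the real 2206 when day 0 replicate 1 joined day 4 replicates 1 and 2.

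The library labelled MDCK-NBL2 untreated day 4 replicate 2 lay with the treated libraries of its line, with a mean correlation of 0.967 to them and of 0.925 to the other untreated replicates. Reads of a treated library mixed in would lower the genes lost with TGFb and raise the genes seen only with TGFb by 1 share, but lost genes called for 92% at the median (quartiles 87.8 to 94.0, 12 genes) and TGFb-only genes for 19.6% (12.8 to 50.4, 22 genes). An exchange of labels with a treated library needs a partner, and 0 of the 3 treated libraries lay nearer to untreated replicates 1 and 3. A culture that received the full treatment would reach treated levels, but 19 of the 22 TGFb-only genes lay below the lowest treated library, where the most for any treated library was 5. These genes were chosen as at least 50 CPM in each of 6 treated libraries, without siRNA or with siCTR, and under 5 CPM in untreated replicates 1 and 3. The choice set a floor for the treated libraries and none for replicate 2. The counts of 19 and 5 are therefore not alike, and alone do not exclude a full treatment. A weaker or later exposure to TGFb, or a change of the culture without it, also stays open and was not tested.

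In MDCK-NBL2 day 0 replicate 1, genes seen in MDCK-II were raised. RNA or reads of MDCK-II in the library are a candidate explanation: the 26 genes lay at a median of 9.69% of their MDCK-II level, with quartiles of 7.93 to 10.7. No MDCK-NBL2 library of day 4 approached these, with upper quartiles of at most 3.53. The genes were chosen as above 20 CPM on average in MDCK-II at day 0 and under 0.5 CPM in MDCK-NBL2 day 0 replicates 2 and 3. The low shares of those replicates were therefore set by the choice. As the cause of all genes raised in the library this stays open, since 7 of 18 raised genes, among them SLC6A17, TGFBI and COL1A2, exceeded what the highest share would bring, and by the same rule 0 genes were raised in replicate 2 and 13 in replicate 3. No biological explanation was tested.

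Interferon response genes were higher with siPRRX1 as a list at the preset correlation (adjusted p = 1.1e-13, with 0.5 with an estimated correlation), most in replicates 2 and 3. MDCK-II RNA is argued against for replicates 2 and 3, where MDCK-II genes were at medians of 0.468% and 0.558% (upper quartiles 3.27 and 3.53) and the pattern would need 39.7% and 21.8% (lower quartiles 28.8 and 16.2). It stays open for the smaller rise in replicate 1, which would need 2.08% (quartiles -1.71 to 5.23) against 0.316% seen (upper quartile 2.34). Delivery of any siRNA is argued against by a median difference of 0.05 between siCTR and no siRNA, against 1.04 between siPRRX1 and siCTR. The SE of 0.04 for the former is over list members, which are not independent replicates, and leaves out the spread between libraries. The later library number series alone is argued against by the smaller of the differences within that series, 1.1, with 31 and 30 of 31 members higher. In replicate 1 the median was 0.55 with 27 of 31 members higher, and 2 of them by 1 or more against 22 and 18 in replicates 2 and 3, although PRRX1 differed there by -4.42 and in the others by -3.23 and -3.13. Whether the pattern follows lower PRRX1 or another effect of this siRNA cannot be told apart, since a single siPRRX1 label was used and replicate 1 is 1 library.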

How the results depend on the processing

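The settings that leave out the doubted library (MDCK-NBL2 untreated day 4 replicate 2), MDCK-NBL2 day 0 replicate 1 or 3 day 4 untreated libraries, and the block in a fit of the compared groups alone, were chosen after the result was seen. Counts of called genes in the 9 comparisons stayed within 1.5 times with DESeq2 size factors in edgeR, with the replicate block over all libraries and with the number series as a term, and so did the shared and moved-back counts with the first 2 of these, the only ones run for them. With DESeq2, the difference of the responses gave 1188 genes, siPRRX1 472 and the TGFb-changed genes moved back 131 (raised) and 73 (lowered); without a filter siPRRX1 gave 163 and the moved-back genes 42 and 25. A 2-fold minimum, which only removes genes, gave 375 and 213 shared rises and falls and 16 and 9 moved back. In fits of the compared groups alone TGFb in MDCK-NBL2 gave 510, the difference 48, siPRRX1 1159 (2528 with the block, where numbers pair), time in MDCK-NBL2 0 by edgeR (1614 at an unadjusted p under 0.05) and the lines at day 4 1267. Without the doubted library siPRRX1 gave 655 and time in MDCK-II 2075. Without the 3 untreated libraries, which leaves 1 in MDCK-NBL2 that is assumed to vary like the other groups, TGFb in MDCK-II gave 5276, the difference 3369, siPRRX1 1589, time 2106 in MDCK-II and 142 in MDCK-NBL2, the lines at day 0 5549, shared rises and falls 1981 and 1943, and moved-back genes 474 and 220. The doubted library is in no group of the siPRRX1 and MDCK-II comparisons. There it can act only through the filter, the scaling and the spread estimated over all libraries, which were not told apart. The cause of the other changes was not tested, apart from the 2-fold minimum. The number of shared or moved-back genes expected if the calls were independent also changes with the setting. The counts of such genes in this part therefore do not measure an excess.

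Leaving out each library of the groups compared in turn gave 1257 to about 2.7e+03 genes for TGFb in MDCK-II, 4457 to 6890 in MDCK-NBL2, 311 to 2653 for the difference, 54 to 234 for siPRRX1, 0 for siCTR, 509 to 1351 for time in MDCK-II, 729 to 5324 in MDCK-NBL2, 3699 to 5998 and 2691 to 3096 between the lines at day 4 and day 0, 498 to 1571 shared rises, 285 to 1396 shared falls, and 22 to 237 and 5 to 96 moved back.

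Directions reversed without the 3 untreated libraries for PDGFRA with TGFb in MDCK-NBL2 (2.24), for MMP13 (3.07) in the difference, and for time in MDCK-NBL2 in FLNC (-0.49), COL27A1 (-0.74), FBLN5 (-0.38), THBS1 (-0.44), ITGB5 (-0.16), SMAD3 (-0.07), ATF3 (-0.22), ALDOC (-0.29) and MEOX1 (-1.03). Without the doubted library alone THBS1 over time was at -0.10 (range over single libraries -0.10 to 2.26), and adjusted list p-values with a reversed direction were 0.00033 for mesenchymal genes, 0.042 for proteases and 0.047 for integrins over time in MDCK-NBL2 (0.5, 0.55 and 0.52 with an estimated correlation), and 0.92 (0.98 with an estimated correlation) for the cell cycle between the lines at day 4; the cause was not tested. Of 69 list calls, 2 held with an estimated correlation, 68 with the block, 57 without the doubted library and 5 with both that library out and an estimated correlation. The self-test, which held no departing library and no pairing, found 56.2% of 2-fold changes in the siPRRX1 comparison.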

Other observations

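The comparison of replicates described in this part was chosen after the result was seen, as were the genes named.

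In treated MDCK-NBL2 cells, with and without siRNA, both PRRX1 and the connective tissue collagen COL3A1 were highest in replicate 1. COL3A1 was at 104, 6.33 and 12 CPM in treated replicates 1, 2 and 3, at 97.5, 6.39 and 10.7 CPM with siCTR and at 4.84, 0.791 and 0.565 CPM with siPRRX1, and PRRX1 at 37.2, 8.89 and 5.71, at 33.9, 7.35 and 3.88, and at 1.11, 0.339 and 0 CPM in the same libraries. Between replicates 2 and 3 PRRX1 was higher in replicate 2 in all 3 groups, and COL3A1 only with siPRRX1. At day 0 replicate 1 was also the highest, with PRRX1 at 7.07 CPM against 0.661 and 0.404 and COL3A1 at 2.49 CPM against 0.0331 and 0. In MDCK-II no library had a COL3A1 count, and PRRX1 reached at most 5.84 CPM. Among the 3 treated groups COL1A1 was highest in replicate 1 only with siPRRX1, with 2110, 2150 and 1060 CPM in treated replicates, 1770, 1940 and 1760 with siCTR and 1500, 1250 and 887 with siPRRX1.

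At day 4 untreated, the log2 difference of MDCK-II replicate 1 from replicates 2 and 3 was set against that of MDCK-NBL2 replicate 1 from replicate 3, without the doubted replicate 2. The latter is a difference between 2 libraries and does not show which of them departs. Across 9456 genes, which are not independent replicates, the differences correlated at r = 0.45 and rho = 0.51. The median difference was -0.63 in MDCK-II and -1.13 in MDCK-NBL2 for the cell cycle list, 0.68 and 0.80 for hypoxia genes, and 1.09 and 0.42 for interferon response genes. Other lists had opposite signs, with -0.11 and 0.95 for ATF4 stress genes, -0.42 and 0.44 for cytokines, 0.56 and -0.06 for cholesterol synthesis, -0.37 and 0.12 for mesenchymal genes and -0.25 and 0.29 for EMT transcription factors.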
